A study of Mus musculus with 15 samples.

How the data were processed

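Gene expression was measured on Visium CytAssist slides, which capture probe ligation products from fixed, paraffin-embedded tissue at barcoded spots, in liver and intestine of wild-type mice. The deposited files hold raw UMI counts per gene and spot for 15 sections, 9 of liver and 6 of intestine. Per the submitters' processing notes the matrices came from Space Ranger 4.0.1 with genome build mm10, and FastQC was also listed. The deposited matrices are the filtered ones, with spots under tissue, and each file holds 1 section. Section thickness, probe set version, the stretch of intestine taken, the sex of each mouse and whether sections of 1 group came from separate mice are not given in the sources used here. Each matrix held 19465 features, of which 70 had no UMI in any section. Features that shared a symbol were kept apart by identifier, and 22 features went by identifier. Gene lists and named genes were matched by symbol.

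Spots are not replicates, so UMIs were summed per section and gene and compared between sections. Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 (17864 genes tested in liver and 19262 in intestine), scaled with TMM factors, and tested with the quasi-likelihood test of edgeR, 2-sided, in 1 fit per tissue over the 3 groups. The Benjamini-Hochberg adjusted p threshold was 0.05 over all genes tested in a comparison. Levels of named genes are CPM of TMM-scaled library sizes, given as the mean and SD over sections, and log2 fold changes are given with their standard error. The common biological coefficient of variation was 0.346 in liver and 0.420 in intestine.

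The comparisons were ethanol against control, ethanol plus FTY720 against ethanol and ethanol plus FTY720 against control in each tissue, the difference of the first 2 effects between tissues (an interaction term over all 15 sections), and the difference of both effects between liver zones. For zones, spots of each liver section were ranked by log2((pericentral UMIs + 1)/(periportal UMIs + 1)), with Glul, Oat, Cyp1a2, Slc1a2, Rgn, Lhpp, Axin2, Tbx3 and Lgr5 as pericentral genes (8 of the 9 were measured) and Cyp2f2, Hal, Sds, Gls2, Hsd17b13 and Ctsc as periportal genes. The highest and lowest of 3 equal parts were summed and compared with section as a block, leaving those genes out of the test. In intestine, mucosa-rich spots were those with more UMIs of the epithelial list than of the smooth muscle list, both left out of that test. The share of spots with at least 1 Igha UMI was taken after thinning every spot to 5000 UMIs and leaving out shallower spots, and was compared with exact permutation tests.

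A set of 47 gene lists (32 used in liver and 33 in intestine) covered immune and other cell types, liver zones, metabolism, stress, cell cycle, clock and intestinal regions. Lists were tested with camera of limma 3.58.1 on the same counts with a preset correlation of 0.01 between genes, which compares a list with all other genes. Camera with an estimated correlation and fry, a test of each list on its own, were run as alternatives. The groups, comparisons, gene lists, tests and a list of other settings were fixed before the data were examined.

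Genes named in the text follow a rule. For ethanol against control and ethanol plus FTY720 against ethanol in each tissue these were the 8 largest increases and the 8 largest decreases among genes past the adjusted p threshold whose sections did not overlap and whose mean was at least 10 CPM in the higher group. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p in that direction were taken and named as not past. The 3 members with the smallest p in the direction of each list past the list test were added. Igha, Jchain, Pigr and S1pr1 were always taken in both tissues, with Fcgr4, Fcer1g, Cd68, Clec4f, Cyp2e1 and Alb in liver and Epcam and Reg3g in intestine. The tests of zones, mucosa-rich spots and tissues name the 5 genes with the smallest p. List members are given as examples, and some results are not reported here.

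The other settings fixed at that stage were RLE factors, no scaling factors, no filter on low counts, only the 2 groups compared, DESeq2 1.42.0, replicate number or accession set as a block, only replicates 2 and 3, spots with at least 1000 UMIs, thinning to the shallowest section, leaving out the 20 most abundant genes, leaving out each section in turn, and other settings for zones, mucosa-rich spots and Igha spots. Added after the data were seen were a block for sex, with and without accession set, only sections without Y-linked signal, leaving out each section for the lists, lists and named genes without scaling factors, a simulation with an ethanol effect only, the reversal measure under other fits, and its covariance with no section in both effects. Sex was inferred from Y-linked genes, with a section read as male above 10 CPM. Spot and figure steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The deposited images and spot coordinates were used only to find neighbouring spots and image scale.

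The fit was tested on simulated data made from the spread in these sections, with 200 changed genes. In the liver ethanol against control comparison it recovered 9.84% of genes changed 2-fold, 71.2% of those changed 4-fold and 95.2% of those changed 8-fold among 17491 genes, with 7 of 120 calls false. For the intestine comparison the shares were 0%, 2.99% and 33.3% among 19252 genes, with 7 of 31 calls false. For the difference between tissues they were 0%, 0% and 16.7% among 19266 genes, with 0 of 11 calls false, and for zones 74.2%, 86.6% and 92.3% among 12720 genes, with 20 of 187 calls false. A T cell list moved 4-fold was recovered by camera in liver with adjusted p = 1.75e-38 at the preset and 0.000241 at the estimated correlation, and in intestine with 2.29e-28 and 0.0387.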

Results

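The data are spatial gene expression profiles of liver and intestine from C57BL/6N mice given a control diet, ethanol, or ethanol with FTY720. FTY720 (fingolimod) is a modulator of sphingosine-1-phosphate receptors that keeps lymphocytes in lymphoid organs, and it was given at 1 mg per kg per day. Liver had 3 sections per group and intestine 2 sections per group. Total UMI counts of control livers 1, 2 and 3 were 43933434, 36565511 and 33214312. Those of ethanol livers were 34674065, 39695861 and 37682488, and those of FTY720 livers 44101995, 39260866 and 49483765. In intestine, control sections 1 and 2 had 24558630 and 46808188 UMIs, ethanol sections 23504966 and 28967283, and FTY720 sections 15626252 and 30573735. Sections held 1646 to 2905 spots, with a median of 17456 to 31219 UMIs per spot in liver and 4922 to 14082 in intestine.

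The labels do not say that sections come from separate mice, so p-values of edgeR and of exact tests measure the spread between sections. Camera at the preset correlation compares the genes of a list with other genes, so its p-values mostly do not measure that spread. Another split of the liver sections gave as many lists as the real one for ethanol against control (16) and FTY720 against ethanol (18). Replicate 1 of every group belongs to a first set of accessions and the other replicates to a second set, with an image scale of 0.036 to 0.048 in the first set and 0.667 in the second. Y-linked genes were at 152 to 194 CPM in control liver 1, ethanol liver 2 and FTY720 liver 2, and at 171 to 205 CPM in control intestine 2 and both FTY720 intestine sections. The remaining sections, among them both ethanol intestine sections, had at most 0.298 CPM of these genes, so sex as inferred from them was mixed within each liver group.

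The comparison of ethanol with control livers asks what chronic ethanol feeding with a binge changed in the liver. The lipid droplet and uptake list was higher and the cholesterol synthesis list lower with ethanol in camera, with adjusted p = 0.0602 and 0.187 when the correlation was estimated. Cidec, a lipid droplet protein that promotes droplet fusion, rose from 1.07 ± 0.45 to 77.4 ± 77.2 CPM (SD, n = 3 per group), a 71.4-fold increase with adjusted p = 0.00396 in edgeR. Mmp12, the macrophage elastase, rose 46.8-fold, from 0.627 ± 0.22 to 29.2 ± 18.2 CPM. Hmgcs1, an enzyme at the start of the mevalonate pathway, fell 7.49-fold, from 325 ± 184 to 43.4 ± 5.39 CPM. Insig1, a regulator of sterol sensing, fell 7.64-fold, from 675 ± 282 to 88.4 ± 28.3 CPM.

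In edgeR, 288 genes passed between ethanol and control livers, 200 higher and 88 lower with ethanol. All 288 had sections that did not overlap, as genes picked by a test on the same sections mostly do, so this adds no support. The share over all genes tested was 18.7%, against 10% by chance. The largest increases also included the metallothioneins Mt2 (66.6-fold) and Mt1 (54.7-fold, from 109 ± 59.9 to 5988 ± 3026 CPM), Wfdc3 (55.5-fold), the epithelial stress gene Sprr1a (33.4-fold), the prostaglandin F receptor Ptgfr (24.1-fold) and Lcn2, an acute phase protein that binds siderophores (23.5-fold, to 205 ± 70.9 CPM). Gngt1 fell 10.9-fold, and Sucnr1, the succinate receptor, fell 7.45-fold. Gask1a, Mvd, Coq8a and Apol7a fell 6.7- to 7.26-fold.

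Gene lists described what moved together, with 16 of 32 liver lists past camera at the preset correlation, 7 higher and 9 lower with ethanol, and none with an estimated correlation (adjusted p from 0.0602). The cholesterol synthesis list had a median log2 fold change of -1.58 (18 of 19 members negative, adjusted p = 3.39e-16 in camera, and 0.187 with an estimated correlation). Of its members 9 passed over all genes and 14 when adjusted over the list alone, among them Hmgcs1, Nsdhl (5.9-fold lower) and Mvd. The fatty acid synthesis list had a median of -0.74 and bile acid genes one of -0.94 (adjusted p = 3.7e-05 and 7.03e-05, against p = 0.344 and p = 0.319 with an estimated correlation). Acly, Fasn and Mlxipl, which make fatty acids or drive their synthesis, had log2 fold changes of -1.80, -1.86 and -1.87 and did not pass, nor did Nr0b2 (-2.09), Cyp8b1 (-1.87) or Abcb11 (-0.91). No member of either list passed over all genes, against 5 and 3 adjusted over the list alone.

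Lipid droplet and uptake genes had a median of 0.91, with 4 of 14 members past over all genes and 7 adjusted over the list alone (adjusted p = 5.74e-06, and 0.0602 with an estimated correlation). Beside Cidec these included the apolipoprotein Apoa4, which rose 13.5-fold to 5464 ± 3051 CPM, and the fatty acid binding protein Fabp4, which rose 5.25-fold. Cell cycle genes had a median of 0.82, and among them the mitotic cyclin gene Ccnb2 rose 3.52-fold and Cdk1, its kinase partner, 3.33-fold (adjusted p = 1.33e-05, and 0.319 with an estimated correlation). Of its members 2 passed over all genes and 6 adjusted over the list alone, and Ccna2 (log2 fold change 1.42) did not pass. The oxidative stress response list had a median of 0.45 (adjusted p = 0.0117, and 0.314 with an estimated correlation). Srxn1, which repairs oxidised peroxiredoxins, rose 12.3-fold, and Gpx3 rose 2.54-fold, while Nqo1 had a log2 fold change of 1.28 and did not pass.

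Immune lists split in direction. B cell genes had a median log2 fold change of -1.25 (13 of 13 negative), plasma cell genes one of -0.83 (17 of 17), NK and cytotoxic genes one of -0.78 (9 of 9) and T cell genes one of -0.59 (13 of 16), with adjusted p from 6.93e-10 to 0.00144 in camera. With an estimated correlation these 4 lists had adjusted p from 0.187 to 0.324. Over all genes 2 B cell and 2 plasma cell members passed, and 10 and 5 did when adjusted over the list alone. Ighd, the heavy chain of naive B cells, fell 4.91-fold, and Igkc, the kappa light chain, fell 4.04-fold, to 10.7 ± 0.978 CPM. Ighm fell by 1.61 and Ms4a1, which encodes CD20, by 1.26 on the log2 scale, while Bank1 (-1.25) and Cd3g (-1.26) did not pass. The acute phase, cytokine and chemokine, and monocyte-derived macrophage lists had medians of 0.51, 0.31 and 0.22 (adjusted p = 0.00448, 0.0186 and 0.0117, and 0.39 to 0.455 with an estimated correlation). In them Gpnmb, a glycoprotein of lipid-laden macrophages, rose 11.3-fold, Cd14, the lipopolysaccharide co-receptor, 6.38-fold, Vcam1, an adhesion molecule, 3.57-fold and Cd9 3.05-fold. Itgax (log2 fold change 2.24) and Ccl2 (1.02) did not pass.

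Pericentral genes, which mark hepatocytes near the central vein where ethanol is oxidised, had a median of -0.94 with 11 of 11 members negative (adjusted p = 7.67e-06, and 0.255 with an estimated correlation). None passed over all genes and 5 did when adjusted over the list alone. Rgn (log2 fold change -2.07), Gulo (-1.20) and Lgr5 (-1.25) were the members with the smallest p. The stellate cell and matrix list had a median of 0.52 and the endothelial list one of -0.36 (adjusted p = 0.013 and 0.0333, and 0.516 and 0.455 with an estimated correlation). Dnase1l3, an endothelial nuclease, fell 2.25-fold. Col1a1 (1.79), Loxl2 (1.31), Timp1 (2.11), Kdr (-1.17) and Ehd3 (-1.02) did not pass.

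The IgA heavy chain Igha was at 5.91 ± 1.96 CPM in control and 2.92 ± 2.36 CPM in ethanol livers (log2 fold change -1.02 ± 0.76, adjusted p = 0.642 in edgeR). Its log2 ratio was 0.51 in the first accession set and -1.83 in the second. Jchain, which joins IgA monomers, was at 3.52 ± 2.04 and 0.963 ± 0.215 CPM (adjusted p = 0.104). Cyp2e1, the cytochrome that oxidises ethanol, was at 3631 ± 627 CPM in control and 1401 ± 1048 CPM in ethanol livers, with adjusted p = 0.214, and 0.0278 with accession set as a block. Log2 fold changes of Pigr, the epithelial IgA transporter (-1.12), Fcgr4 (0.66), Fcer1g (-0.31), Cd68 (0.41), the Kupffer cell lectin Clec4f (0.21), S1pr1 (-0.61) and Alb (-0.10) did not pass either. The remaining 16 lists did not pass, with medians from -0.70 for alcohol and drug metabolism to 0.08 for resident macrophages. In 5 of them the median and the test differed in sign, among them resident macrophage and interferon-stimulated genes. Scaling moved the median of all genes from 0.10 without factors to -0.05.

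**Figure D1:**
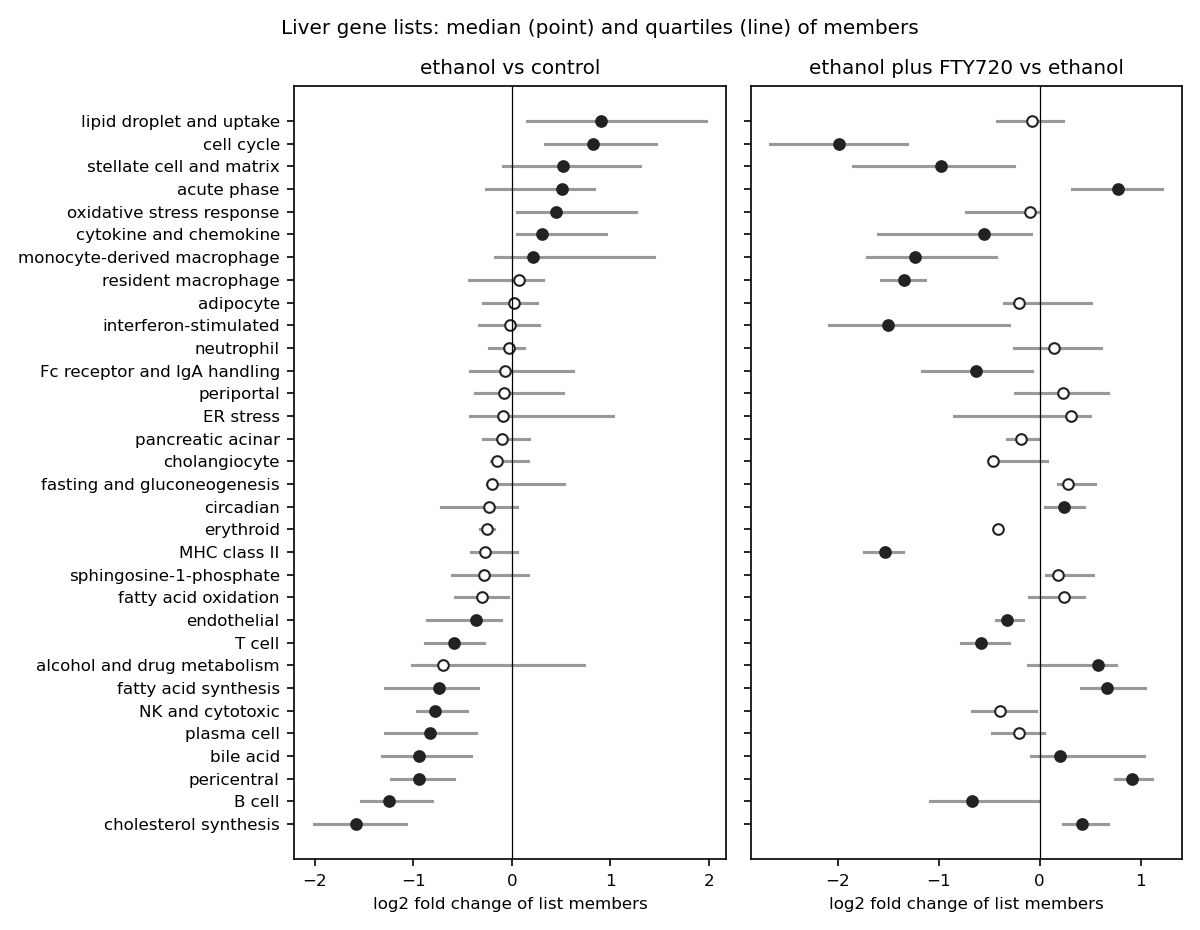
Each point is the median log2 fold change of the members of a gene list in liver and each line spans their quartiles, for ethanol against control (left) and ethanol plus FTY720 against ethanol (right), with filled points for lists past camera at the preset correlation. Cholesterol synthesis was at -1.58 on the left and 0.42 on the right, and cell cycle at 0.82 and -1.99.

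The count for ethanol against control was 1738 with accession set as a block, 399 over replicates 2 and 3 alone, 256 with a block for sex and 913 in DESeq2. It was 97 without ethanol section 1, 40 without control section 2, 57 without control section 3 and 125 without ethanol section 3. Log2 ratios in the first and second accession set were 6.33 and 4.67 for Cidec, 5.32 and 4.37 for Mmp12, -2.58 and -3.00 for Hmgcs1 and -0.59 and -2.38 for Igkc. With accession set as a block, genes named above as not past had adjusted p from 0.00379 to 0.0437, except Ccl2, Pigr, Fcgr4, S1pr1, Igha, Fcer1g, Cd68, Clec4f and Alb (0.0709 to 0.886).

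The comparison of FTY720 with ethanol livers asks what the drug changed in mice that drank ethanol. Macrophage, matrix, cell cycle and interferon lists were lower with FTY720 in camera, with adjusted p from 0.0748 to 0.131 when the correlation was estimated. Mmp12 fell 25-fold, from 29.2 ± 18.2 to 1.16 ± 0.24 CPM (SD, n = 3 per group, adjusted p = 0.0178 in edgeR). The fibrillar collagen genes Col3a1 and Col1a1 fell 10.9-fold, from 100.1 ± 45.7 to 9.22 ± 1.16 CPM, and 8.26-fold, from 55.6 ± 28.4 to 6.72 ± 0.633 CPM. Mki67, a marker of dividing cells, fell 6.67-fold, from 12.4 ± 5.13 to 1.87 ± 0.702 CPM. Acot11, an acyl-CoA thioesterase, rose 6.04-fold, from 3.12 ± 0.546 to 18.8 ± 3.88 CPM.

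In edgeR 64 genes passed, 5 higher and 59 lower with FTY720. Slc34a2, a phosphate transporter (13.1-fold), Lrtm1 (5.71-fold), Dclk3 (4.82-fold) and the Wnt ligand Wnt11 (3.28-fold) were the other increases. Among the largest decreases were Wfdc3 (43.3-fold), the protease inhibitor Slpi (10.5-fold) and the mitotic genes Knstrn (9.62-fold) and Cdca3 (6.8-fold).

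Of the 32 lists 18 passed camera, 7 higher and 11 lower, and none did with an estimated correlation (adjusted p from 0.0748). Cell cycle genes had a median log2 fold change of -1.99, with 12 of 12 members negative, 5 past over all genes and 9 adjusted over the list alone (adjusted p = 1.12e-16, and 0.0967 with an estimated correlation). Ccnb2 fell 6.86-fold, Ccna2 6.52-fold and Cdk1 6.3-fold. Resident macrophage genes had a median of -1.34, with 13 of 13 negative, 3 past over all genes and 11 adjusted over the list alone (adjusted p = 1.6e-14, and 0.0748 with an estimated correlation). Cd5l, a secreted Kupffer cell protein, fell 4.31-fold, from 391 ± 157 to 90.7 ± 14.3 CPM. Adgre1, which encodes F4/80, fell 3.29-fold, from 7.51 ± 1.14 to 2.28 ± 0.369 CPM, and the receptor Csf1r fell 2.54-fold, from 57.2 ± 7.93 to 22.5 ± 1.95 CPM. Monocyte-derived macrophage genes had a median of -1.23 (12 of 14 negative, adjusted p = 2.76e-07, and 0.131 with an estimated correlation). Of these Gpnmb fell 11.6-fold and the integrin gene Itgax fell by 3.59 on the log2 scale with no UMI in 1 FTY720 section, while Trem2 (-2.98) did not pass.

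Interferon-stimulated genes had a median of -1.50, with 16 of 19 negative, 3 past over all genes and 12 adjusted over the list alone (adjusted p = 7.01e-13, and 0.131 with an estimated correlation). Rsad2, an antiviral enzyme, fell 6.11-fold, Ifit1 4.89-fold and the transcription factor Irf7 4.53-fold. MHC class II genes had a median of -1.54, all 9 negative, with none past over all genes and 7 adjusted over the list alone; H2-Eb1 (-2.14), H2-Ab1 (-1.75) and Ciita (-1.26) did not pass. The stellate cell and matrix list had a median of -0.98, with 16 of 17 negative, and Acta2 (-1.60) in it did not pass. Monocyte-derived macrophage and matrix lists each had 2 members past over all genes, with 7 and 9 adjusted over the list alone. Adjusted p of the MHC class II and matrix lists was 1.91e-08 and 9.31e-09 in camera and 0.131 each with an estimated correlation. Fc receptor and IgA handling genes had a median of -0.63 and cytokine and chemokine genes one of -0.55, in which the inhibitory lectin receptor Clec4a2 fell 4.69-fold and Vcam1 4.91-fold (adjusted p = 0.000122 and 5.22e-05, and 0.0748 and 0.131 with an estimated correlation). Fcgr1 (-1.85), Ccl4 (-3.25) and Ccl5 (-2.07) did not pass. B cell, T cell and endothelial lists had medians of -0.67, -0.58 and -0.32 (adjusted p = 0.000231 to 0.0142, and 0.251 to 0.328 with an estimated correlation). In them no member passed over all genes, with Bank1 at -1.46, Ighd at -1.44, Cd79b at -1.29, Ccr7 at -1.47 and Clec4g at -0.75.

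The 20 most abundant genes held 33.0 to 36.3% of UMIs in FTY720 livers and 27.6 to 29.6% in ethanol livers. Pericentral genes had a median of 0.91 (10 of 11 positive), acute phase genes one of 0.78 (17 of 19), fatty acid synthesis genes one of 0.67 and alcohol and drug metabolism genes one of 0.58 (adjusted p = 2.76e-07, 2.01e-06, 0.000441 and 0.00173). With an estimated correlation these adjusted p were 0.131, 0.186, 0.333 and 0.131. Over all genes no member passed, with Cyp2e1 at 1.73, Lcn2 at 1.69, Orm3 at 2.81, Orm2 at 1.76, Pklr at 1.40, Fasn at 1.31, Por at 0.88, Aldh2 at 0.91, Slc1a2 at 1.08 and Tbx3 at 1.58. Cholesterol synthesis, circadian and bile acid lists had medians of 0.42, 0.24 and 0.20 with TMM factors and 0.02, -0.13 and -0.07 without, where the median of all genes was -0.36 against 0.01 with factors. Their adjusted p was 0.000129, 0.0492 and 0.00947, and 0.186 to 0.391 with an estimated correlation. Nsdhl (1.08), Dhcr7 (0.98), Cry1 (0.63), Cyp8b1 (1.82), Cyp27a1 (1.06) and Slc10a1 (1.03) did not pass.

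Igha was at 2.92 ± 2.36 CPM in ethanol and 2.11 ± 1.69 CPM in FTY720 livers (log2 fold change -0.47 ± 0.76, adjusted p = 0.973 in edgeR), with log2 ratios of -0.56 and -0.18 in the accession sets. Log2 fold changes of Jchain (0.04), Pigr (0.82), Fcgr4 (-0.88), Fcer1g (-0.83), Clec4f (-1.16), S1pr1 (0.53) and Alb (0.67) did not pass. Cd68, a lysosomal protein of macrophages, had -1.57 ± 0.30 and adjusted p = 0.0624, and 0.00591 with accession set as a block. The plasma cell list had a median of -0.20 (adjusted p = 0.499), lipid droplet and uptake genes one of -0.07 (adjusted p = 0.818), and the other 12 lists that did not pass had medians from -0.46 for cholangiocyte to 0.31 for ER stress genes.

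**Figure D2:**
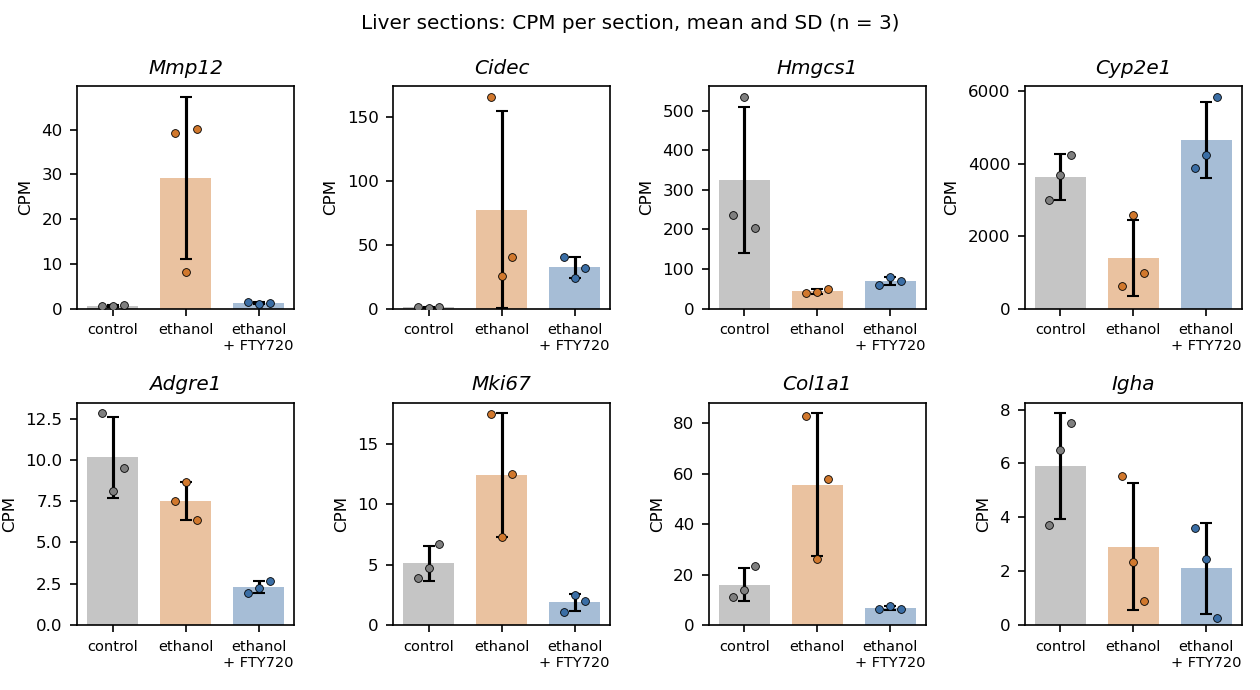
CPM of 8 genes in liver sections (points), with bars for the group mean and whiskers for the SD (n = 3). Mmp12 and Mki67 were highest with ethanol and at 1.16 and 1.87 CPM with FTY720, and Adgre1 was at 2.28 CPM with FTY720.

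The count for FTY720 against ethanol was 655 with accession set as a block, 14 over replicates 2 and 3 alone, 212 without scaling factors, 461 in DESeq2 and 0 in edgeR with only the 2 groups in the fit. It was 17 without ethanol section 1, 210 without ethanol section 2, 1 without FTY720 section 1 or 2, and 0 without ethanol section 3 or FTY720 section 3. Median log2 ratios in the first and second accession set were -1.68 and -1.16 for resident macrophage genes and -1.88 and -1.33 for cell cycle genes, and those of Col1a1 were -3.63 and -2.51. With accession set as a block, Fcgr1, Tbx3, Ccl4, Bank1, Trem2, Acta2, Cyp8b1, Ccl5, H2-Eb1, Cyp2e1, Clec4f, Orm3, Ccr7, Lcn2, Fcer1g, H2-Ab1, Pklr and Slc10a1 had adjusted p from 0.00463 to 0.0473. Other genes named above as not past, apart from Cd68, had 0.0529 or more.

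The comparison of FTY720 with control livers asks what separated livers with ethanol and drug from those with neither. B cell, T cell and resident macrophage lists were lower than in control and the acute phase list higher in camera, with adjusted p from 0.0934 to 0.105 when the correlation was estimated. B cell genes had a median log2 fold change of -1.84 (13 of 13 negative, 7 past over all genes, 11 adjusted over the list alone), MHC class II genes one of -1.77 (9 of 9), interferon-stimulated genes one of -1.52 (18 of 19) and NK and cytotoxic genes one of -1.34 (9 of 9). Resident macrophage genes had one of -1.29 (11 of 13), T cell genes one of -1.25 (14 of 16) and cholesterol synthesis genes one of -1.25 (17 of 19). Acute phase and lipid droplet genes had medians of 0.88 (16 of 19 positive) and 0.82 (12 of 14).

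Over all genes 7 interferon-stimulated, 5 cholesterol synthesis, 4 resident macrophage and 2 T cell members passed, and 13, 13, 10 and 11 did when adjusted over the list alone. The 9 lists named so far had adjusted p from 3.21e-14 to 3.37e-05 in camera, and from 0.063 to 0.219 with an estimated correlation. Cell cycle, endothelial, plasma cell, stellate cell and matrix, and Fc receptor lists also passed, with medians of -1.07, -0.74, -0.71, -0.63 and -0.47 and adjusted p up to 0.00501 (0.0934 to 0.429 with an estimated correlation). The monocyte-derived macrophage list had a median of -0.78 and adjusted p = 0.0667, and the other 17 lists that did not pass had medians from -0.72 for erythroid to 0.61 for fasting genes. In 3 of these (adipocyte, neutrophil and fatty acid oxidation) the median and the test differed in sign. Fcer1g, the signalling chain shared by activating Fc receptors, fell 2.2-fold, from 72.6 ± 9.33 to 33 ± 5.39 CPM (SD, n = 3, adjusted p = 0.0351 in edgeR). Igha (-1.49), Jchain (-1.82), Cd68 (-1.16), Clec4f (-0.95), Pigr (-0.30), Fcgr4 (-0.21), Cyp2e1 (0.36), S1pr1 (-0.08) and Alb (0.57) did not pass. Jchain, Cd68 and Clec4f had adjusted p = 0.0294, 0.00705 and 0.0172 with accession set as a block.

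In edgeR 469 genes passed, 199 higher and 270 lower with FTY720, and without scaling factors 508 did, 129 higher and 379 lower. The median of all genes was -0.04 with factors and -0.28 without. The count was 2055 with accession set as a block, 707 over replicates 2 and 3 alone, 202 over sections without Y-linked signal and 1080 in DESeq2. It was 182 without FTY720 section 1, 135 without FTY720 section 2, 210 without FTY720 section 3, 117 without control section 2 and 91 without control section 3.

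Whether FTY720 moved the ethanol-responsive genes back was asked by comparing the 2 effects gene by gene. Of the 288 genes, 78.8% had the opposite sign under FTY720 (95% interval 73.6 to 83.4). The interval takes genes as independent and leaves out the spread between sections. The share was 72.2% without ethanol liver 1 and 90.1% without ethanol liver 2. Both effects share the ethanol sections, and simulated data with no effect gave 91.3% (87.2 to 95.8) while data with an ethanol effect only gave 66.7% (59.7 to 71.5). Each draw used its 288 genes of smallest p. The draws with an ethanol effect only took the estimated fold changes as true. In them a median of 968 genes passed (843 to 1069), against 288 in the data. That effect was stronger than in the data, so values from these draws are no like benchmark. The covariance of both effects over genes was -0.141, against -0.0990 ± 0.00373 (SD of 100 draws) with no effect and -0.100 ± 0.00497 with an ethanol effect only. Of the genes past both tests, 15 were higher with ethanol and lower with FTY720, 1 was lower and then higher, and none moved the same way in both, against 0.661, 0.0246, 0.0560 and 0.291 for independent lists, which leave out the shared sections. As many genes of smallest p gave 6 (1 to 12) and 13 (4 to 19) in simulated data with no effect, and 2 (0 to 6) and 3 (0 to 9) with an ethanol effect only. The 16 genes were Mmp12, Gpnmb, Vcam1, Wfdc3, Slpi, Rsad2, Mthfd2, Btc, Pi16 and the cell division genes Ccnb2, Cdk1, Cdkn3, Hmmr, Ckap2 and Knstrn, with Dclk3 as the lower one. With no section in both effects the covariance was -0.132 and -0.0974 when the effects came from different accession sets, and 0.0624 and 0.0104 when they came from separate ethanol sections of the second set. Simulated values of these 4 lay between -0.0187 and 0.0178. The value of 0.0624 set an ethanol section read as male against control sections read as female. Its FTY720 effect set sections of both sexes against an ethanol section read as female. Sex thus entered both effects in the same direction there, and the simulated data held no sex effect. With the ethanol sections of the second set in both effects it was -0.0894, against -0.142 in data with no effect, and why these values differ was not tested. Part of the excess may come from the shared ethanol sections, and whether the drug moved the genes back stays open.

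Zones of the liver were compared to ask whether effects differed between pericentral and periportal spots. Under ethanol the pericentral to periportal ratio moved for 59 genes in edgeR, 45 towards pericentral and 14 towards periportal. Ces1g, a carboxylesterase, went from a log2 ratio of 0.34 ± 0.07 in control to 1.49 ± 0.08 in ethanol livers (SD, n = 3), a difference in the fit of 1.09 ± 0.10 with adjusted p = 0.00081 in edgeR. Ccnd1, the G1 cyclin, went from -0.83 ± 0.23 to 0.41 ± 0.10. Sdsl went from -3.29 to -2.11, the mitochondrial kinase Ak4 from -1.81 to -0.62 and the serine transporter Sfxn1 from -2.49 to -0.92. The score that bounded the pericentral part was at least 2.75 in control and at most 1.21 in ethanol sections, so the parts compared may not be like zones, and poorer separation would pull such ratios towards 0. Cyp2e1 in pericentral spots was at 6753 ± 267 CPM in control, 3092 ± 1533 CPM in ethanol and 7116 ± 1812 CPM in FTY720 livers.

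Under FTY720 the ratio moved for 21 genes, 11 towards pericentral and 10 towards periportal. The score that bounded the pericentral part was at most 1.21 in ethanol and at least 1.85 in FTY720 sections. The parts compared may thus not be like zones here either. Cth, an enzyme that makes cysteine, went from -0.64 ± 0.25 in ethanol to 0.55 ± 0.10 in FTY720 livers (SD, n = 3), Trp53inp1, a p53 target, from -0.09 to 1.05, Fmo2 from 0.18 to 1.10 and the purine synthesis enzyme Paics from -0.24 to 0.57. Derl3, an ER stress gene, went from -0.02 to -1.97, at 0.889 CPM in pericentral and 5.15 CPM in periportal spots of FTY720 livers. Counts without ethanol section 2 were 531 and 411. The ethanol count was 10 to 27 without any 1 of the control sections or ethanol section 1 (control 1 27, control 2 17, control 3 10, ethanol 1 14), and the FTY720 count was 1 without ethanol section 1, 13 without FTY720 section 1 and 0 without FTY720 section 3.

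Igha spots were counted to ask where IgA transcripts lay. In liver 1.37 ± 0.308% of spots had an Igha UMI in control, 1.02 ± 0.706% in ethanol and 0.554 ± 0.484% in FTY720 sections (SD, n = 3). Differences were -0.353 percentage points for ethanol against control, -0.461 for FTY720 against ethanol and -0.814 for FTY720 against control, with 2-sided exact permutation p = 0.6, 0.5 and 0.2, where the smallest possible is 0.1. The first 2 became -0.0852 and -0.729 without ethanol liver 3, and -0.754 and -0.0610 without ethanol liver 1. Jchain spots were 1.02 ± 0.0940%, 0.469 ± 0.0689% and 0.281 ± 0.107%, with exact p = 0.1 in each comparison, the smallest possible. In intestine Igha spots were 98.8 ± 0.241%, 95.2 ± 1.77% and 97.5 ± 3.27% (SD, n = 2), near saturation, with exact permutation p = 0.333 for ethanol against control, 0.667 for FTY720 against ethanol and 1 for FTY720 against control, where the smallest possible is 0.333. Thinning left out 193 to 227 spots per liver group and 1605 to 1931 per intestine group.

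A concentration of macrophage genes in liver spots with IgA transcripts was not detected. The log2 ratio of macrophage genes (resident and monocyte-derived lists) between Igha spots and other spots was 0.09 ± 0.30 (SD over 9 sections, 6 of 9 above 0, 2-sided exact sign-flip p = 0.410, smallest possible 0.00391). Spots were not thinned for this test, which left 52 to 101 Igha spots per control, 24 to 97 per ethanol and 12 to 68 per FTY720 section. Without FTY720 liver 3, which had 12 such spots, the mean was 0.0173. With Igha spots and their nearest neighbours pooled against all other spots it was 0.07 (exact p = 0.406). In Igha spots endothelial, neutrophil and alcohol metabolism lists gave 0.03, -0.14 and -0.03 (exact p = 0.469, 0.414 and 0.613). B cell genes gave 0.25 ± 0.86 in Igha spots (5 of 9 above 0, exact p = 0.383) and 0.09 with neighbours (4 of 9, exact p = 0.387). In Jchain spots they gave 0.39 ± 0.37, above 0 in 9 of 9 sections (exact p = 0.00391, the smallest possible). T cell and cholangiocyte genes gave -0.28 and -0.41 there, each above 0 in 2 of 9 (exact sign-flip p = 0.227 and 0.0859). Macrophage genes gave 0.07 in Jchain spots (6 of 9 above 0, exact sign-flip p = 0.418). B cell, T cell and cholangiocyte lists were not among those planned for this test, and these p-values are unadjusted. Differences of the macrophage ratio between groups were 0.11, 0.13 and 0.24 (exact permutation p = 0.6, 0.7 and 0.6), and as low as -0.0394, -0.11 and -0.000328 without 1 section. With Jchain spots they were 0.32, -0.36 and -0.0427 (exact permutation p = 0.1, 0.1 and 0.8, smallest possible 0.1).

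The comparison of ethanol with control intestine asks what ethanol changed at the site where IgA is made. No gene passed in edgeR (0 of 19262), with 501 at an unadjusted p under 0.05 and 143 past in DESeq2. Those 501 are fewer than chance alone gives at 0.05. Lists differed in camera at the preset correlation, and 0 did with an estimated correlation. Fry gave 0 lists by direction (adjusted p from 0.123) and 5 for change in either direction. Plasma cell genes had a median log2 fold change of -1.31 (17 of 18 negative), B cell genes one of -1.05 (14 of 14), cell cycle genes one of -1.11 (11 of 12) and antimicrobial genes one of -1.47 (11 of 13), while adipocyte genes had one of 2.21 (8 of 8 positive). Adjusted p of these 5 lists in camera was 5.8e-10 or less, and 0.162 to 0.198 with an estimated correlation. Igha was at 9127 ± 1228 CPM in control and 3867 ± 533 CPM in ethanol sections (SD, n = 2, log2 fold change -1.24 ± 1.01), with a ratio of -1.24 in each accession set.

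No member of any list passed over all genes. When adjusted over the list alone, 1 plasma cell, 3 B cell, 1 cell cycle and 5 adipocyte members passed, with 5 lower and 1 higher antimicrobial members. Genes with the smallest p, none past the threshold (adjusted p = 1 in edgeR), were higher with ethanol for the adipose genes Car3 (24.3 ± 11.6 to 195 ± 22.8 CPM), Plin1 (log2 fold change 2.80), Cfd (3.54) and Lep (2.07) and for Thrsp (2.37). They were lower for Gsdmc3, a gasdermin of the gut epithelium (138 ± 105 to 4.84 ± 0.464 CPM), Gsdmc4 (-5.75), Pla2g4c (-5.57), the hydrogen peroxide-producing oxidase Duox2 (95.9 ± 47.3 to 10.7 ± 3.8 CPM) and Ighg3 (45 ± 15.8 to 8.06 ± 0.838 CPM). Jchain, at 2627 ± 2333 CPM in control and 715 ± 490 CPM in ethanol sections, and Mzb1, a chaperone of plasma cells (-1.83), Iglc1 (-2.61), Fcer2a (-2.33), Cr2 (-1.55), Mcm5 (-1.98) and Duoxa2 (-1.91) did not pass either. Pigr (-0.54), Epcam (-0.62), Reg3g (-1.60) and S1pr1 (0.33) were in the same position.

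Of 33 intestine lists 16 passed camera for ethanol against control, 4 higher and 12 lower, and none did with an estimated correlation (adjusted p from 0.162). IgA induction and gut homing genes had a median of -0.57 (15 of 18 negative), with Ccr10, the homing receptor of IgA plasma cells, at -1.19. Tuft cell genes had -0.75, MHC class II -0.52, interferon-stimulated -0.50, goblet -0.49, Fc receptor -0.44, T cell -0.42 and monocyte-derived macrophage genes -0.28, while enteric neuron and glia had 0.52, erythroid 0.36 and circadian genes 0.24. These 11 lists had adjusted p from 0.000994 to 0.0341, and from 0.196 to 0.525 with an estimated correlation. The 17 others had medians from -0.58 for ER stress to 0.17 for neutrophil genes, and in 2 of them, crypt stem and sphingosine-1-phosphate, the median and the test differed in sign. Scaling moved the median of all genes from 0.20 without factors to 0.00. Mucosa-rich spots were 84.2 and 93.7% of spots in control and 80.3 and 70.8% in ethanol sections. Lists were not tested within these spots, so tissue make-up may add to the differences of lists. Non-overlapping sections were found for 21.7% of genes, against 33.3% by chance with 2 sections per group. The count was 9 without control section 1 and 164 with accession set as a block, which in intestine is the same as replicate number, and in the first and second set the medians were -1.06 and -1.48 for plasma cell and -0.49 and -1.58 for B cell genes. With this block, genes named above had adjusted p from 0.0021 to 0.0401, except Cr2, Ccr10, Jchain, Igha, Epcam, Pigr and S1pr1 (0.0688 to 0.598).

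The comparison of FTY720 with ethanol intestine asks what the drug changed there. Ileum, goblet, Paneth and smooth muscle lists were lower and B, plasma and T cell lists higher with FTY720 in camera, with adjusted p from 0.195 to 0.251 when the correlation was estimated. The ileum list had a median log2 fold change of -2.14 (5 of 5 negative, adjusted p = 2.55e-09 in camera, and 0.195 with an estimated correlation), with 3 members past when adjusted over the list alone. Slc10a2, the bile acid transporter of the ileum, was at 1238 ± 1564 CPM in ethanol and 7 ± 1.12 CPM in FTY720 sections (SD, n = 2), and Fgf15, the ileal hormone that responds to bile acids, at 27.9 ± 3.6 and 6.44 ± 2.15 CPM. Goblet genes had a median of -1.28 (12 of 12 negative) with the mucin Muc2 at -2.31 ± 0.82, Paneth genes one of -1.40 (7 of 7) and antimicrobial genes one of -1.01 (9 of 13) with the lectin Reg3b at -4.36 ± 1.21. B cell genes had 1.07 (14 of 14 positive) and plasma cell genes 0.82 (16 of 18).

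Camera gave these 5 lists adjusted p of 2.9e-06 or less, and 0.195 to 0.211 with an estimated correlation. No gene passed in edgeR (0 genes, with 346 at an unadjusted p under 0.05 and 64 past in DESeq2), so the values of single genes are given without a call. Those 346 are fewer than chance alone gives at 0.05. Igha was at 3867 ± 533 CPM in ethanol and 10636 ± 9311 CPM in FTY720 sections (log2 fold change 1.46 ± 1.01), with a ratio of 2.30 in the first accession set and -0.07 in the second. The smallest p belonged to the globin genes Hbb-bt (6.5 ± 0.589 to 29.7 ± 5.56 CPM) and Hbb-bs (2.19), Gkn3 (1.98), the checkpoint receptor Ctla4 (2.52) and P2ry10 (1.64) among higher genes. Among lower genes it belonged to Nos2, the inducible nitric oxide synthase (40.7 ± 4.05 to 6.27 ± 0.026 CPM), Suox (-3.34), P2ry4 (-3.03), Bex1 (-2.57) and Slc10a2. Retnlb had 0.337 ± 0.179 CPM in ethanol and no UMI in FTY720 sections. Jchain (0.80), Pigr (-1.07), Epcam (-0.34), Reg3g (-2.47) and S1pr1 (0.64) did not pass.

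Of the 33 lists 22 passed camera, 11 in each direction, and none did with an estimated correlation (adjusted p from 0.195). Erythroid genes had a median of 2.09 (5 of 5 positive, 3 past over the list alone), interferon-stimulated genes 1.17, cell cycle genes 0.68, IgA induction and gut homing genes 0.61, T cell and neutrophil genes 0.57 each, resident macrophage genes 0.45, pancreatic acinar genes 0.29 and cytokine genes 0.20. Among these Ccr7, which guides naive lymphocytes, was at 1.64, Madcam1, the gut addressin, at 1.01, Rsad2 at 2.98 and Ifi44 at 2.36. Adipocyte genes had -1.36, circadian genes -0.95 with Dbp at -2.37, smooth muscle genes -0.93 (10 of 10 negative), tight junction genes -0.54, enteric neuron and glia -0.36, epithelial genes -0.35 and crypt stem genes -0.33 with the Wnt targets Axin2 and Ascl2 at -1.45 and -1.42. Adjusted p of these 16 lists was 2.05e-08 to 0.0287 in camera, and 0.196 to 0.518 with an estimated correlation. The proximal small intestine list had a median of 1.41 (adjusted p = 0.0538, and 0.00274 without scaling factors), and the other 10 had medians from -0.40 for MHC class II to 0.50 for Fc receptor genes, with the test of opposite sign to the median in colon and monocyte-derived macrophage genes.

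Both FTY720 intestine sections carried Y-linked signal and neither ethanol section did, so sex and drug coincide in this comparison. Within the first and second accession set the medians were -2.25 and -2.09 for ileum, -0.05 and 1.51 for interferon-stimulated and -0.08 and 1.74 for proximal small intestine genes. The count was 205 with accession set as a block and 7 with only the 2 groups in the fit, 25.8% of genes had sections that did not overlap (33.3% by chance), and scaling moved the median of all genes from 0.33 to 0.06. With this block, genes named above had adjusted p from 0.00122 to 0.0472, except Pigr, Ifi44, Madcam1, Retnlb, Ascl2, Rsad2, Igha, S1pr1, Jchain and Epcam (0.0922 to 0.53).

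**Figure D3:**
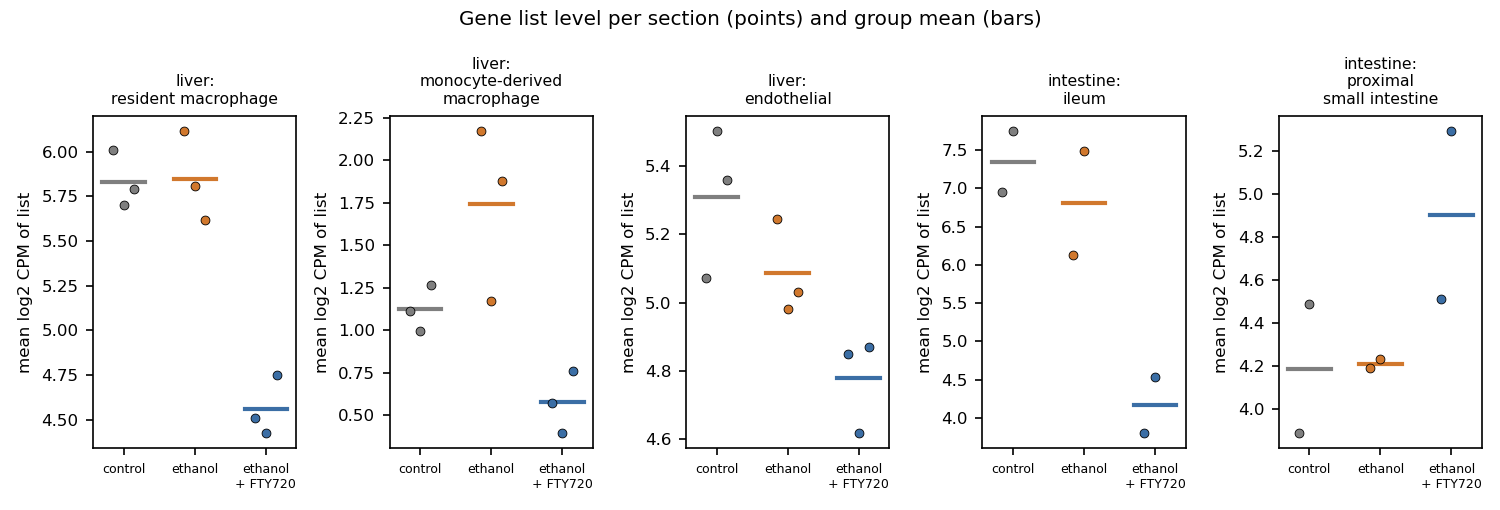
Mean log2 CPM of the members of 5 gene lists per section (points) with the group mean (lines), 3 sections per group in liver and 2 in intestine. Resident macrophage genes were at 4.42 to 4.75 in FTY720 livers and 5.62 to 6.11 in ethanol livers, and ileum genes at 3.80 and 4.54 in FTY720 intestine against 6.13 and 7.49 in ethanol intestine.

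FTY720 was also compared with control intestine, to ask what separated drug-treated from untreated sections. The antimicrobial list had a median log2 fold change of -2.33 (12 of 13 negative), ileum -2.85 (4 of 5), goblet -1.93 (12 of 12) and Paneth -1.69 (7 of 7), and erythroid genes had 2.49 (5 of 5 positive), with adjusted p of 3.4e-07 or less in camera and 0.146 to 0.359 with an estimated correlation. Adjusted over the list alone 9 goblet members, 9 lower and 1 higher antimicrobial members, 4 ileum and 3 erythroid members passed. Summed ileum genes were at 2507 ± 1489 CPM in control and 295 ± 231 CPM in FTY720 sections. Summed proximal small intestine genes were at 355 ± 270 and 661 ± 492 CPM, so sampling of another stretch of intestine stays open. Both FTY720 sections and control section 2 read as male and control section 1 as female, so sex is partly mixed with the drug. Reg3g, a bactericidal lectin, was at 5615 ± 3860 CPM in control and 334 ± 320 CPM in FTY720 sections (SD, n = 2, log2 fold change -4.07 ± 1.30, adjusted p = 0.822 in edgeR). Igha was at 9127 ± 1228 and 10636 ± 9311 CPM (0.22 ± 0.99, adjusted p = 0.935), with ratios of 1.06 and -1.30 in the accession sets.

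The other 11 of the 16 lists past camera were lower for epithelial (-0.96), tuft (-0.88), MHC class II (-0.87), smooth muscle (-0.84), tight junction (-0.75), crypt stem (-0.67), plasma cell (-0.65) and cell cycle genes (-0.60) and higher for adipocyte (0.94), neutrophil (0.68) and pancreatic acinar genes (0.39). Their adjusted p was 5.57e-05 to 0.0405, and 0.256 to 0.474 with an estimated correlation. Of these the plasma cell median was 0.02 without scaling factors, where the median of all genes was 0.54 against 0.08 with factors. The 17 lists that did not pass had medians from -0.59 for absorptive enterocyte to 0.82 for proximal small intestine genes, and in 3 of them (B cell, Fc receptor, and IgA induction and gut homing) the median and the test differed in sign. Jchain (-1.08), Pigr (-1.61), Epcam (-0.96) and S1pr1 (0.97) did not pass. Fewer genes had an unadjusted p under 0.05 than chance alone gives. No gene passed in edgeR (0 genes, 748 at an unadjusted p under 0.05, 311 past in DESeq2), 32.6% had sections that did not overlap (33.3% by chance), and the count was 2 without control section 1 or 2, 1 without FTY720 section 2, and 1418 with accession set as a block, where Reg3g and Pigr had adjusted p = 0.000172 and 0.00866.

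Mucosa-rich spots, 70.8 to 93.7% of spots per section, were compared to ask whether differences lay in the epithelial layer. In the first and second accession set their share was 84.2 and 93.7% in control and 80.3 and 70.8% in ethanol sections. In FTY720 sections it was 83.7 and 91.6%, so the ethanol section had the lowest share in each set. No gene passed in edgeR for ethanol against control (418 at an unadjusted p under 0.05) or FTY720 against ethanol (399), and no other tool was run. Genes with the smallest p were Gsdmc3 (log2 fold change -4.68), Pla2g4c (-5.45), Ighg3 (-2.83), Duox2 (-3.07) and Gsdmc4 (-5.62) for ethanol, and Nos2 (-2.88), Hbb-bt (2.35), Gkn3 (2.09), Suox (-3.56) and P2ry4 (-3.17) for FTY720. The counts were 170 and 418 with accession set as a block, and 9 for ethanol without control section 1 and 1 for FTY720 without ethanol section 1.

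Effects were compared between tissues to ask whether liver and intestine responded alike. For FTY720 against ethanol 15 genes differed in edgeR (n = 3 liver and 2 intestine sections per group), 3 with a higher and 12 with a lower effect in liver. The intestine part of this term set ethanol sections read as female against FTY720 sections read as male, so sex and drug coincide in it. Sampling of another stretch of intestine stays open there as well. The spindle protein gene Prc1 went from 5.07 to 0.363 CPM in liver and from 24.0 to 42.9 CPM in intestine, a difference of -4.70 ± 0.68 on the log2 scale (adjusted p = 0.0462 in edgeR). Ccna2 went from 8.42 to 1.29 CPM in liver and from 54.7 to 97.9 CPM in intestine (-3.60), and the division genes Racgap1 (-3.33) and Dlgap5 (-3.46) differed the same way. Suox, the mitochondrial sulfite oxidase, went from 118 to 179 CPM in liver and from 226 to 22.3 CPM in intestine (3.90).

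For ethanol no gene differed between tissues in edgeR (0 genes, 1292 at an unadjusted p under 0.05, no other tool run), with the smallest adjusted p of 0.0696 for Ptgfr (4.65) and Pla2g4c (5.04), then 0.161 for Gsdmc4 (5.85), Mmp12 (4.98) and Specc1 (2.93). Igha had a difference between tissues of 0.22 ± 1.23 for ethanol (adjusted p = 1 in edgeR) and -1.99 ± 1.24 for FTY720 (adjusted p = 0.925). Jchain (-0.04 and -0.81), Pigr (-0.62 and 1.86) and S1pr1 (-0.97 and -0.14) did not pass. The FTY720 count was 81 without scaling factors, where the median of all genes was -0.66 against -0.05 with them, and 815 with accession set as a block within each tissue. It was 74 without ethanol liver 2, 5 without ethanol intestine 1, 2 without FTY720 intestine 1, 1 without ethanol liver 1, and 0 without ethanol liver 3, ethanol intestine 2, FTY720 intestine 2 or any 1 of the FTY720 livers. For ethanol it was 502 with accession set as a block, 32 without ethanol liver 2 and 3 without control intestine 1.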

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

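The tests of a difference between tissues and between zones were fixed beforehand, and the counts over other splits of the sections were chosen after the results were seen. A difference between tissues in the response to FTY720 was found for 15 genes in edgeR by an interaction term. The 5 with the smallest p had log2 differences, liver minus intestine, of -4.70 for Prc1, -3.33 for Racgap1, -3.46 for Dlgap5, 3.90 for Suox and -3.60 for Ccna2. In the intestine part of this term sex and drug coincide, and another stretch of intestine stays open, so these are not shown to be drug effects. Without 1 section the count ranged from 0 (without ethanol liver 3, ethanol intestine 2, FTY720 intestine 2, or FTY720 liver 1, 2 or 3) to 74 (without ethanol liver 2), and it was 1 without ethanol liver 1, 2 without FTY720 intestine 1 and 5 without ethanol intestine 1.

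A difference between liver zones in the response to ethanol was found for 59 genes, with log2 differences of 1.09 for Ces1g, 1.23 for Sdsl, 1.12 for Ak4, 1.49 for Sfxn1 and 1.16 for Ccnd1. A difference between zones in the response to FTY720 was found for 21 genes, with 1.26 for Cth, 1.01 for Fmo2, 1.21 for Trp53inp1, 0.88 for Paics and -2.43 for Derl3. In both cases the score that bounded the pericentral part differed between the groups, so the parts compared may not be like zones. Of the 10 splits of the 6 sections compared, 1, the real one, gave as many genes for ethanol (59, highest other split 2) and 1 for FTY720 (21, highest other split 2). With 10 splits the share cannot go under 0.05. Without ethanol liver 2 the counts were 531 and 411. Without control liver 1, 2 or 3 or ethanol liver 1 the ethanol count was 27, 17, 10 or 14, and without ethanol liver 1, FTY720 liver 1 or FTY720 liver 3 the FTY720 count was 1, 13 or 0.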

How the results depend on the processing

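Settings named as added were chosen after the data were seen. The liver counts stayed within 1.5 times of 288, 64 and 469 with RLE factors, no filter, spots of at least 1000 UMIs, thinning, and without the 20 most abundant genes. They were 913, 461 and 1080 in DESeq2, and 1738, 655 and 2055 with accession set as a block. With replicate number as a block they were 1816, 821 and 2147. The numbers do not pair the livers, since 6 of 9 sections resembled their own number most and same-number correlations fell to 0.0623, and in intestine (0.706 to 0.792) the 2 numbers are the accession sets. With the added block for accession set and sex the counts were 2537, 1369 and 2785. Only the 2 groups compared gave 164 for ethanol against control and 0 for FTY720 against ethanol, and replicates 2 and 3 alone gave 14 for FTY720 against ethanol and 707 for FTY720 against control, both with fewer sections. No scaling factors gave 212 for FTY720 against ethanol, and the added fit of sections without Y-linked signal gave 202 for FTY720 against control. Leaving out 1 section gave 40 to 362, 0 to 210 and 91 to 521 genes.

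In intestine the counts of 0 became 143, 64 and 311 in DESeq2 and 164, 205 and 1418 with the block, and FTY720 against ethanol gave 7 with 2 groups in the fit. Leaving out 1 section gave 0 to 9, 0 and 0 to 2. Mucosa-rich spots gave 170 and 418 with the block, and 0 to 9 and 0 to 1 without 1 section. The difference between tissues gave 1 gene for ethanol and 81 for FTY720 without factors, 502 and 815 with the block within each tissue, and 0 to 32 and 0 to 74 without 1 section. Zones gave 33 genes for FTY720 with 4 equal parts in place of 3, and 10 to 531 for ethanol and 0 to 411 for FTY720 without 1 section.

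Lists past the test numbered 0 in all 6 comparisons with an estimated correlation. Directional fry gave 4 and 5 in liver for ethanol against control and FTY720 against ethanol, and 0, 0 and 5 in intestine for the 3 comparisons. Mixed fry, which counts change in either direction, gave 25 in liver for ethanol against control and 5, 2 and 6 in intestine. Without 1 section, as added, the lists numbered 12 to 15, 16 to 21 and 14 to 18 in liver and 11 to 14, 18 to 21 and 11 to 19 in intestine.

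The share of genes with opposite signs was 64.1% over all genes and 84.6% without factors (added), and 72.2 to 90.1% without 1 section (72.2% without ethanol liver 1 and 90.1% without ethanol liver 2). The covariance of both effects with no section in both, as added, was -0.132 to 0.0624. Liver Igha shares differed by -0.353, -0.461 and -0.814 points, and by -1.03, -0.598 and -1.63 without thinning, -0.167, -0.265 and -0.432 at 2000 UMIs (exact p = 0.5, 0.4 and 0.1), -0.395, -0.0417 and -0.437 at 2 UMIs (exact p = 0.1, 0.8 and 0.1) and -0.554, -0.188 and -0.742 for Jchain. Without 1 section they differed by -0.754 to -0.0852, -0.729 to -0.0610 and -1.05 to -0.569. Intestine shares differed by -3.59 points for ethanol against control, and by -9.78 at 2000 UMIs, -7.59 at 2 UMIs and -13.6 for Jchain, with -4.84 to -2.34 without 1 section. For FTY720 against ethanol they differed by 2.36, and by 7.90, 5.53 and 11.7, with 0.0428 to 4.67, and for FTY720 against control by -1.24, and by -1.88, -2.06 and -1.93, with -3.55 to 1.08. Without thinning the intestine differences were -4.03, 4.95 and 0.921, the last of opposite sign. The macrophage ratio with Jchain in place of Igha was 0.32 for ethanol against control (0.11 with Igha, exact p = 0.1, the smallest possible), -0.36 for FTY720 against ethanol (exact p = 0.1) and -0.0427 for FTY720 against control, both reversed. With nearest neighbours the 3 differences were 0.0257, 0.0962 and 0.12, and without 1 section they were -0.0394 to 0.25, -0.11 to 0.29 and -0.000328 to 0.40.

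Of 2480 settings over 275 named gene results, 2046 kept direction and side of the threshold, 201 came past it, 215 fell short of it and 18 reversed, 16 of these without 1 section and 2 without factors. Of the 201, 98 came past with replicate number as a block and 71 in DESeq2. In liver the reversals were Clec4f for ethanol against control (-0.15 to 0.42), Alb (-0.23 to 0.00741, and 0.0392 without factors), Igha for FTY720 against ethanol (-1.12 to 0.40, and 0.06 without FTY720 liver 3) and Jchain (-0.30 to 0.39, and -0.32 without factors). In intestine they were Uchl1 (-0.0947 to 1.61) and Pigr (-0.93 to 0.00247) for ethanol, and C1qa (-0.0212 to 1.22), Cd68 (-0.11 to 0.96), S100a9 (-0.23 to 1.71), Rsad2 (-0.18 to 3.89), Amy2a5 (-0.0533 to 1.07) and Vil1 (-1.35 to 0.0501) for FTY720 against ethanol. Where a left-out section leaves 1 in a group, that section is taken to vary like the others. Apart from the settings with fewer sections, the cause was not tested.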

Other observations

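All tests of explanations and counts over other splits in this part were chosen after the results were seen. Some liver lists have not been set side by side over the 3 comparisons so far. Lipid droplet and uptake genes had a median log2 fold change of 0.91 for ethanol against control, -0.07 for FTY720 against ethanol and 0.82 for FTY720 against control, with summed levels of 1467 ± 158 CPM in control, 7237 ± 3579 CPM in ethanol and 4223 ± 655 CPM in FTY720 livers (SD, n = 3). Acute phase genes had 0.51, 0.78 and 0.88. B cell genes had -1.25, -0.67 and -1.84, with summed levels of 32.0 ± 3.56 CPM in control, 12.6 ± 3.77 CPM in ethanol and 6.70 ± 0.81 CPM in FTY720 livers (SD, n = 3). Summed T cell genes were at 28.1 ± 8.45, 17.7 ± 1.4 and 12.3 ± 1.15 CPM. Pericentral genes, at 9353 ± 1717, 4041 ± 2315 and 8938 ± 1104 CPM, had a median of -0.03 for FTY720 against control.

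In intestine, summed B cell genes were at 411 ± 73.7 CPM in control, 207 ± 73 CPM in ethanol and 443 ± 23.2 CPM in FTY720 sections (SD, n = 2), and erythroid genes at 50.2 ± 6, 78.1 ± 4.81 and 327 ± 97.7 CPM. Y-linked genes marked control liver 1, ethanol liver 2 and FTY720 liver 2 as male, and in intestine control 2 and both FTY720 sections. Liver and intestine sections of 1 group and number differed in sex for control 1, control 2, ethanol 2 and FTY720 1, so these pairs cannot come from 1 mouse each.

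Resident macrophage genes were lower in FTY720 than in ethanol livers, with a median log2 fold change of -1.34 (adjusted p = 1.6e-14 in camera, and 0.0748 with an estimated correlation). More hepatocyte RNA in the FTY720 sections would lower endothelial genes as much, yet the macrophage list fell by 0.98 relative to the endothelial list, with SDs of 0.111 and 0.152 and no overlap between groups. A difference between the accession sets would leave 1 set without the change, but the set nearer 0 had -1.16 and the other -1.68. Sections without Y-linked signal gave -1.43, which argues against sex as the whole cause. Each liver group also held the same mix of sets and of inferred sexes, so an offset equal in all groups would cancel. Fewer resident macrophages under FTY720, or lower expression of these genes in each, may therefore account for it, which counts of stained macrophages per section would tell apart.

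Ileum genes were lower in FTY720 than in ethanol intestine, with a median of -2.14 (adjusted p = 2.55e-09 in camera, and 0.195 with an estimated correlation). Sampling of another stretch of intestine stays open, since the mean level of the proximal list differed by 0.32 in 1 accession set and 1.06 in the other, with 1 section per group in each. Lower expression of ileal genes with the drug stays open as well. In mucosa-rich spots the median was -2.29, but such spots need only more epithelial than smooth muscle UMIs. Their share of epithelium may thus differ between groups, so less epithelium stays open. Summed epithelial genes over whole sections were at 16152 ± 6581 CPM in ethanol and 11050 ± 3711 CPM in FTY720 sections. Sex cannot be told apart from the drug here, as both ethanol sections read female and both FTY720 sections male, and the 1 male control section had an ileum level 0.79 above that of the 1 female control section.

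Pericentral genes were lower in ethanol than in control livers, with a median of -0.94 (adjusted p = 7.67e-06 in camera, and 0.255 with an estimated correlation). Fewer pericentral spots in the ethanol sections would leave the most pericentral 5% of spots at control levels, but there Cyp2e1, which did not rank the spots, was at a log2 CPM of 13.00 to 13.06 in control and 11.54 to 12.62 in ethanol sections. Gulo, which did not rank them either, was at 9.51 to 10.61 and 8.93 to 9.55, so its groups overlapped and fewer such spots stay open for the list as a whole. The accession set nearer 0 had a list median of -0.75 and the other -1.14, and sections without Y-linked signal had -1.30. These values argue against set or sex, each taken alone, as the whole cause. The section read as male was in the first set in control and in the second in ethanol livers. Each check thus leaves the other factor in. Each liver group also held the same mix of sets and of inferred sexes, so an offset equal in all groups would cancel. A lower level of Cyp2e1 within pericentral spots after ethanol is a hypothesis in line with these values.

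Other splits of the 6 liver sections compared were counted for each result, with 10 splits in each case, too few for a share under 0.05. For genes, 1 of the 10 splits, the real one, gave as many in each comparison, with 288, 64 and 469 genes against at most 1, 0 and 0 in the others. For lists, 2 of the 10 splits gave as many as the 16 for ethanol against control, the second being control 1, control 2 and ethanol 2 against the rest with 16. For FTY720 against ethanol 2 of the 10 gave 18, the second being ethanol 1, ethanol 3 and FTY720 3 against the rest, and for FTY720 against control 1 of the 10 gave 14, with at most 12 in the others.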
